A study of Arabidopsis thaliana with 18 samples.

How the data were processed

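The series measured transcripts of the tip section of roots in 18 libraries, 2 for each of 9 groups. Per the labels' protocols, seedlings grew vertically on 0.5x MS medium under continuous light for 7 days, received 100 nM BL, 5 µM IAA, both, or a mock solution for 4 h where treated, and total RNA was made into TruSeq libraries. The deposited files hold, per library, raw whole-number read counts for each Arabidopsis locus, with no normalization. Per the submitters' processing notes, TopHat 1.4.0, Bowtie and HTSeq were used with the TAIR10 genome build. The annotation release, the strand setting and any filters are not given in the sources used here, nor is which step each tool performed. Each file lists 33602 loci and 5 closing lines for reads assigned to no gene, which were left out of all totals. Gene symbols came from the TAIR10.1 RefSeq annotation, which matched 32835 loci and gave 10654 a symbol. Locus identifiers were matched and no coordinates were used.

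Counts assigned to genes ranged from 11225390 to 36431707 per library, and 22164 to 23564 loci had at least 1 count. The 10 most abundant loci took 3.33% to 4.84% of the counts. Reads outside genes made up 5.87% to 7.25% at 101 bp and 10.9% to 12.0% at 36 bp, and the part that aligned to more than 1 place was 3.05% to 4.45% at 101 bp and 8.19% to 9.35% at 36 bp. Because read length coincides with the experiment, the 12 libraries of 101 bp and the 6 of 36 bp were fitted apart. A fit of all 18 served to test whether the BL response differed between dwf4 and Col-0, and as an alternative for the other comparisons. Counts between the 2 libraries of a group varied more than counting error alone, with a chi-square per degree of freedom of 1.83 to 5.75 over loci with at least 20 counts in the pair, and no 2 files were identical. A locus with no counts in a library could have been present at up to the level of 3 counts, 0.0823 to 0.267 CPM. This floor covers counting error only and did not enter the fits, which used the counts unchanged.

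Groups were compared with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with TMM factors, filterByExpr by group (minimum count 10, minimum total count 15), 1 coefficient per group, the quasi-likelihood F test and Benjamini-Hochberg adjustment within each comparison, at an adjusted p of 0.05. The fits tested 20644, 19558 and 20393 genes with common biological coefficients of variation of 0.0483, 0.0723 and 0.0557, residual degrees of freedom of 6, 3 and 9 and prior degrees of freedom of 10.2, 5.48 and 7.95 for the 12, 6 and 18 libraries. CPM in the text are scaled by the TMM-adjusted library size. Fold changes are log2 and used a prior count of 0.125. The 13 comparisons covered single and combined hormones, their interaction, the mutants against their controls, BL in dwf4, and the difference between the BL responses. The bri1-116 and double mutant libraries were untreated, so their contrasts with Col-0 set untreated against mock-treated roots. BL-treated dwf4 was set against untreated roots, with no mock group at 36 bp, so BL and the handling of the treatment are confounded there. With 2 libraries per group, tests on permuted labels or for outliers would have little power, and none was run. The numbering of replicates was not used as a block, because the labels do not say that equal numbers belong together.

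The test was tried on simulated data in which 200 genes were changed 1.5-fold, 2-fold or 4-fold in counts with the estimated spread. For BL against mock it recovered 75.8% of the 1.5-fold and 86.4% of the 2-fold changes. For BL in dwf4 the shares were 30.3% and 73.2%, and for the interaction 40.3% and 80.3%. False calls made up 2.78% to 10.9% of calls, depending on the comparison. Each comparison was simulated once. Most comparisons called far more than 200 genes in the data, so recovery there may differ.

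Comparisons, tests, alternatives, the rule for named genes and 29 gene lists were chosen before the data were examined, apart from exceptions stated below. The lists held 357 members, of which 3 were dropped because the annotation gives the locus another symbol: PRE2 (BNQ2) and PRE4 (BNQ3) of the growth-related bHLH list and SGN3 (GSO1) of the endodermis list. The 354 others cover 352 distinct loci, since EXPA7 and EXPA18 are both expansins and root hair genes. The lists were tested with camera at a preset correlation of 0.01, with camera at the estimated correlation, and with fry, each adjusted across the 29 lists of a comparison. The directional form of fry tests whether the genes of a list move on balance one way and the mixed form whether they change in either direction, and neither compares a list with other genes. Counts adjusted over the list alone apply the adjustment to the list's own p-values.

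Named genes were, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall that had a symbol, a mean of at least 2 CPM over the libraries compared, and every library of one group above every library of the other. For the interaction and the difference of BL responses they were 6 each way without the condition on libraries. Up to 4 members per list with the smallest adjusted p were added, any other list member could be named with its value, and DWF4, BRI1 and BZR1 were given throughout. The value of 1 list member that is withheld for evaluation is not reported here.

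Agreement between comparisons used Pearson and Spearman correlations of log2 fold changes across genes and counts of genes called in both, set against the number expected from the list sizes. Where 2 comparisons share libraries, counts were simulated for unchanged groups with the estimated spread in 10 draws to give the correlation and covariance that the sharing alone makes. A control group of 2 libraries leaves 1 per contrast when split, so calls were not compared after a split, and part of an excess of shared calls may come from the shared control. Correlations with a separate mock library for each contrast were added after the results were seen. The alternatives tried were DESeq2 size factors, library totals, no low-count filter, a mean of at least 2 CPM, an adjusted p of 0.01, a test against a fold change of 1.5 (glmTreat), only the groups compared, all 18 libraries, DESeq2 1.42.0 (Wald test), the replicate number as a block, and leaving out each library in turn. For agreement they also included a prior count of 5 and only genes called in either comparison. The replicate block was not a planned setting for agreement. When a group was left with 1 library, that library was taken to vary like the other groups.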

Results

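RNA was sequenced from the tip section of roots of 7-day-old Arabidopsis thaliana seedlings, in 18 libraries that fell into 9 groups of 2. Wild-type Col-0 seedlings received a mock solution, 100 nM brassinolide (BL, the most active brassinosteroid), 5 µM indole-3-acetic acid (IAA, the main natural auxin), or both hormones, each for 4 h. Untreated bri1-116, a mutant of the brassinosteroid receptor, and the untreated bri1-116 bzr1-1D double mutant, which adds a dominant form of the transcription factor BZR1 (AT1G75080), were sequenced with these groups at 101 bp. A separate set at 36 bp held untreated wild type, untreated dwf4, a mutant of a brassinosteroid synthesis enzyme, and dwf4 given BL for 4 h. Counts assigned to genes ranged from 11225390 to 36431707 per library at 101 bp and from 11764200 to 15647439 at 36 bp. A transcript with no counts in a library could have been present at up to 0.0823 to 0.267 CPM (counts scaled to a total of 1e6), the level that 3 counts give, a floor that covers counting error only. The 2 libraries of a group correlated at r = 0.990 (dwf4 untreated) to r = 0.997 (Col-0 IAA) across genes on the log2 CPM scale. All values below are CPM as mean ± SD of n = 2 libraries, or log2 fold changes with their standard error. Calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The p-values of these calls measure only the spread between these samples. The labels do not say whether the 2 libraries of a group came from separate cultures. Those of camera and of Fisher's exact test set genes against other genes instead.

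DWF4 (AT3G50660), which encodes a hydroxylase of brassinosteroid synthesis, stood at 44.8 ± 1.79 CPM in mock-treated Col-0 and fell to 30.2 ± 2.68 with BL (log2 fold change -0.58, SE 0.0810, adjusted p = 0.000207). With IAA it rose to 117 ± 1.85 CPM, and with both hormones it stood at 81.3 ± 7.24. In dwf4 the DWF4 transcript was at 48.1 ± 0.626 CPM against 50.8 ± 1.51 in wild type, a difference that did not pass the test (adjusted p = 0.493). BL lowered it in dwf4 to 24.3 ± 0.344 CPM. BRI1 (AT4G39400), the receptor gene, fell with BL in Col-0 from 122 ± 10.7 to 80.4 ± 10.6 CPM and in dwf4 to 87.9 ± 0.795 CPM (log2 fold change -0.91, SE 0.0830, adjusted p = 0.000321). In bri1-116 the BRI1 transcript was at 139 ± 4.66 CPM (adjusted p = 0.0692 against mock-treated Col-0) and in the double mutant at 108 ± 6.15 CPM. BZR1 lay between 26.8 ± 0.854 CPM in mock-treated Col-0 and 33.6 ± 0.577 CPM in BL-treated dwf4. Transcript levels of DWF4, BRI1 and BZR1 do not check the genotype labels, because these alleles need not alter the amount of transcript. The labels do not name the dwf4 allele, so that genotype could not be checked from counts.

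**Figure D1:**
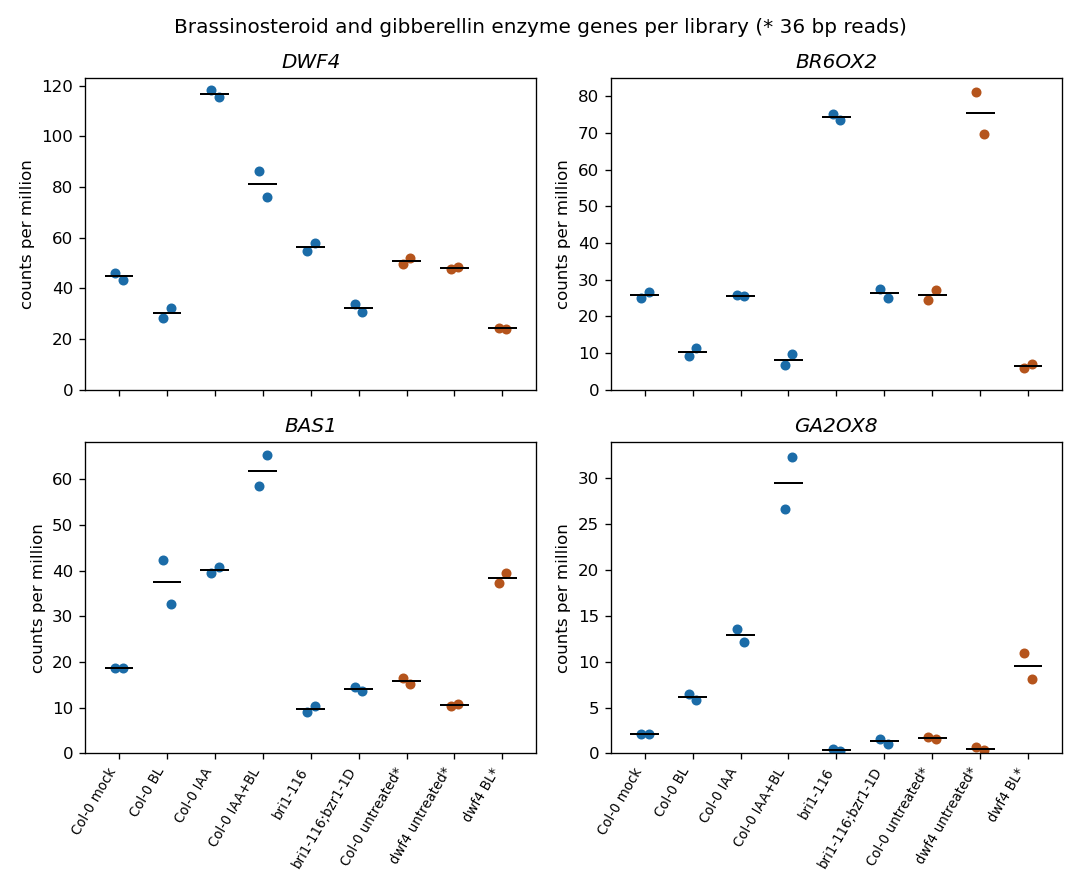
Each point is 1 library and each bar the mean of 2, in CPM, for DWF4 and BR6OX2 (brassinosteroid synthesis), BAS1 (brassinosteroid inactivation) and GA2OX8 (gibberellin inactivation) in the 9 groups, with the 36 bp groups in orange. BR6OX2 is at 74.4 ± 1.11 CPM in bri1-116 and 75.5 ± 8.02 CPM in untreated dwf4 and lowest, 6.51 ± 0.864 CPM, in BL-treated dwf4.

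The first comparison asked which root transcripts respond to BL within 4 h in wild type. BL raised ACS9 (AT3G49700), an ethylene-precursor synthase gene, from 1.48 ± 0.547 to 8.57 ± 1.57 CPM (log2 fold change 2.53, SE 0.225, adjusted p = 2.16e-06), and the sulfate transporter gene SULTR1;1 (AT4G08620) from 7.20 ± 2.07 to 40.4 ± 2.38 CPM (2.46, SE 0.135, adjusted p = 3.32e-08). The auxin synthesis gene YUC3 (AT1G04610) rose from 22.7 ± 2.63 to 57.5 ± 6.89 CPM, and the expansin-like gene EXLA2 (AT4G38400) from 9.83 ± 0.132 to 24.5 ± 1.13 CPM. BR6OX2 (AT3G30180), whose product catalyses the last steps to BL, fell from 25.9 ± 1.16 to 10.3 ± 1.63 CPM (-1.37, SE 0.116, adjusted p = 1.33e-06), and the cytokinin-response regulator ARR3 (AT1G59940) fell from 20.2 ± 0.193 to 6.46 ± 0.674 CPM (-1.62, SE 0.110, adjusted p = 1.78e-07). Other large rises were NCED9 2.08, PERK4 1.61, GA2OX8 (AT4G21200) 1.57 and LAF1 1.42 on the log2 scale, and other large falls were ATGSTF13 -2.35, HSFA2 -1.84, MYB55 -1.54 and RTFL15 -1.59.

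Among gene lists, 9 of 16 genes for xyloglucan endotransglucosylases, which remodel the cell wall, rose and 1 fell (10 and 2 adjusted over the list alone). The median was 0.32 (camera adjusted p = 2.15e-05, and adjusted p = 0.0667 with an estimated correlation). Risers were XTH4 0.81, XTH31 0.80 and XTH12 0.63, and XTH24 fell (-1.18). Of the auxin-induced Aux/IAA repressor genes, 11 of 26 measured rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000115, and adjusted p = 0.106 with an estimated correlation), led by IAA5 1.78, IAA33 1.22 and IAA19 0.83. In brassinosteroid synthesis, 0 of 10 genes rose and 4 fell (the same adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.000115, and adjusted p = 0.0667 with an estimated correlation): the 4 were BR6OX2 -1.37, CPD -0.62, DWF4 -0.58 and DWF1 -0.26. Of the brassinosteroid-inactivating enzymes, 2 of 4 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.000395, and adjusted p = 0.0667 with an estimated correlation), namely BAS1 1.03 and SOB7 0.46. Of 6 PLETHORA-family genes, which maintain the root stem cell niche, 4 fell: PLT2 -1.14, PLT3 -1.12, PLT1 -0.76 and BBM -0.60, while PLT5 (adjusted p = 0.467) and PLT7 (adjusted p = 0.391) did not pass the test. They belong to the stem cell and meristem regulators, of which 1 of 15 rose and 4 fell (2 and 5 adjusted over the list alone). The median was -0.06 (camera adjusted p = 0.00585, and adjusted p = 0.106 with an estimated correlation). The mitotic list of 20 genes had 0 risers and 0 fallers, also when adjusted over the list alone (camera adjusted p = 0.501). In total 2675 of 20644 tested genes were called, 1315 higher and 1360 lower, and 199 changed more than 2-fold. The count was 1150 without mock replicate 1, 1657 without mock replicate 2 and 1551 without BL replicate 2. With DESeq2 it was 1679, and with a fit of the 4 libraries compared alone 1577.

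The response to IAA was measured in the same way. GH3.3 (AT2G23170), an auxin-conjugating enzyme gene, rose from 9.40 ± 1.08 to 2319 ± 133 CPM (log2 fold change 7.94, SE 0.201, adjusted p = 8.31e-15), and MES17 (AT3G10870), whose product hydrolyses methylated IAA, from 3.39 ± 0.0889 to 242 ± 0.00318 CPM (6.15, SE 0.129, adjusted p = 8.4e-16). LBD33 (AT5G06080), of a family that acts in lateral root formation, rose from 0.441 ± 0.385 to 36.3 ± 5.05 CPM. The aquaporin genes NLM1 (AT4G19030) and TIP2;3 (AT5G47450) fell from 113 ± 5.31 to 3.81 ± 0.572 CPM and from 165 ± 18.6 to 7.34 ± 0.591 CPM (-4.93 and -4.47 on the log2 scale). SKOR (AT3G02850), a potassium channel of the stele, fell from 15.7 ± 2.62 to 0.636 ± 0.0480 CPM.

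Auxin-response lists moved together: 5 of 6 GH3 genes rose and 1 fell (the same adjusted over the list alone), with a median of 5.03 (camera adjusted p = 3.35e-35, and adjusted p = 0.00391 with an estimated correlation), and 5 of 6 lateral root LBD genes rose and 1 fell (the same adjusted over the list alone). The median was 4.61 (camera adjusted p = 2.87e-29, and adjusted p = 0.000673 with an estimated correlation). Of the Aux/IAA genes, 21 of 26 rose and 2 fell (the same adjusted over the list alone), with a median of 1.93 (camera adjusted p = 1.81e-41, and adjusted p = 0.0027 with an estimated correlation), with IAA19 at 4.78 and IAA28 at -0.69. Among root hair genes, 0 of 18 genes rose and 17 fell (the same adjusted over the list alone), with a median of -0.59 (camera adjusted p = 1.39e-05, and adjusted p = 0.304 with an estimated correlation); examples were IRE -1.33, RSL4 -1.22, MRH6 -1.07 and LRX1 -0.83. Primary-wall cellulose synthesis had 0 risers and 7 fallers among 8 members (the same adjusted over the list alone). The median was -0.53 (camera adjusted p = 0.0029, and adjusted p = 0.344 with an estimated correlation). The brassinosteroid synthesis list held 1 riser, DWF4 (1.39), and 8 fallers among 10 genes, including BR6OX1 -1.93, ROT3 -0.68 and CPD -0.63, with the same counts adjusted over the list alone (camera adjusted p = 0.0934, not past the threshold). Of the inactivating enzymes, 3 of 4 rose and 0 fell (the same adjusted over the list alone). The median was 1.65 (camera adjusted p = 0.0029, and adjusted p = 0.0662 with an estimated correlation). The stress and handling list, which holds touch, wound and heat genes, moved too: 9 of 12 rose and 0 fell (the same adjusted over the list alone), with a median of 0.82 (camera adjusted p = 0.00748, and adjusted p = 0.344 with an estimated correlation), with TCH3 2.26 and ZAT10 (AT1G27730) 2.00. Shoot-type photosynthesis genes had 8 fallers and 0 risers of 10, the same when adjusted over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.416 with an estimated correlation). ACT2, often used as a reference gene, fell by 1.14 on the log2 scale. IAA changed 12236 of 20644 genes, 6179 higher and 6057 lower, and 2829 by more than 2-fold.

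With both hormones, GH3.3 stood at 2178 ± 93.2 CPM against 9.40 ± 1.08 in mock, and CYP78A10 (AT1G74110), a cytochrome P450 gene, rose from 0.415 ± 0.00968 to 49.1 ± 7.74 CPM. GSTU14 (AT1G27140), a glutathione transferase gene, fell from 32.0 ± 1.03 to 0.321 ± 0.0615 CPM (log2 fold change -6.58, SE 0.198, adjusted p = 7.25e-14). Every one of the 18 root hair genes fell against mock, also when adjusted over the list alone, with a median of -1.16 (camera adjusted p = 2.99e-17, and adjusted p = 0.0617 with an estimated correlation). Of the auxin transport genes, 11 of 17 rose and 4 fell (the same adjusted over the list alone), with a median of 0.66 (camera adjusted p = 4.82e-09, and adjusted p = 0.0248 with an estimated correlation), and of the brassinosteroid-inactivating enzymes, 4 of 4 rose and 0 fell (the same adjusted over the list alone). The median was 1.77 (camera adjusted p = 2.58e-05, and adjusted p = 0.0248 with an estimated correlation). GH3 and Aux/IAA genes had 6 of 6 and 22 of 26 risers, the same counts adjusted over each list alone (adjusted p = 0.0022 and 0.000882 with an estimated correlation). Against mock, 10741 genes were called, 5361 higher and 5380 lower. Against BL alone, IAA changed 11611 genes, 5878 higher and 5733 lower. The fold changes of the combined treatment correlated across genes with those of IAA alone at r = 0.917, with the sum of the 2 single responses at 0.902 and with BL alone at 0.091. The shared mock libraries alone gave r = 0.453, 0.511 and 0.418 in simulated unchanged groups, and the covariances above the simulated ones were 0.741, 0.757 and 0.0154. With a separate mock library for each contrast, r was 0.84 and 0.839 with IAA alone and 0.07 and 0.006 with BL alone, over the 2 ways to split.

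In the presence of IAA, BL raised the amino acid transporter gene UMAMIT35 (AT1G60050) from 6.92 ± 0.163 to 41.0 ± 10.7 CPM (log2 fold change 2.54, SE 0.174, adjusted p = 1.55e-07) and BGAL4 (AT5G56870), a beta-galactosidase gene, with a log2 fold change of 1.77 (SE 0.0850, adjusted p = 4.32e-09). BR6OX2 fell from 25.6 ± 0.129 to 8.18 ± 2.05 CPM, ACS11 (AT4G08040) from 11.5 ± 0.883 to 1.27 ± 0.716 CPM, and ZAT10, a stress-responsive zinc finger gene, from 30.0 ± 1.54 to 6.76 ± 0.934 CPM. Of the root hair genes, 0 of 18 rose and 16 fell (0 and 17 adjusted over the list alone). The median was -0.51 (camera adjusted p = 6.99e-26, and adjusted p = 0.11 with an estimated correlation). Of the stress and handling genes, 0 of 12 rose and 9 fell (1 and 10 adjusted over the list alone). The median was -0.61 (camera adjusted p = 1.24e-07, and adjusted p = 0.148 with an estimated correlation). Of the brassinosteroid synthesis genes, 0 of 10 rose and 4 fell (the same adjusted over the list alone). The median was -0.17 (camera adjusted p = 2.09e-05, and adjusted p = 0.113 with an estimated correlation). BL changed 2174 genes against IAA alone, 1115 higher (51.3%) and 1059 lower, a share that was 69.0% with library totals in place of the composition factors. The count was 1104 without IAA replicate 1, 1099 without IAA replicate 2 and 1285 without IAA plus BL replicate 2. Of the 2675 genes called for BL without IAA, 87% had the same sign with IAA present and 918 were also called with that sign.

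The BL by IAA interaction tested whether the BL response differed with IAA present, a question the series title raises by naming antagonism between the hormones. In the root hair list, 0 of 18 genes had a positive and 12 a negative interaction (0 and 17 adjusted over the list alone). The median was -0.68 (camera adjusted p = 5.22e-53, and adjusted p = 0.0197 with an estimated correlation). EXPA7 (AT1G12560), an expansin of hair cells, was at 55.5 ± 2.25 CPM in mock, 62.0 ± 1.39 with BL, 41.0 ± 0.753 with IAA and 21.5 ± 1.13 with both (interaction adjusted p = 3.35e-05). Others were PRP1 (AT1G54970) (interaction -1.04, SE 0.0990, adjusted p = 3.57e-05), MRH6 -0.96 and RHS12 -0.90. Without IAA, BL raised 6 and lowered 2 of these 18 genes (adjusted over the list alone, 9 and 2). Of the xyloglucan endotransglucosylase genes, 2 of 16 had a positive and 5 a negative interaction (4 and 9 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 1.06e-05, and adjusted p = 0.13 with an estimated correlation), with XTH13 -0.91, XTH12 -0.84, XTH24 0.70 and XTH5 0.65. In the cytokinin list, 1 of 13 genes had a positive and 0 a negative interaction (8 and 0 adjusted over the list alone). The median was 0.36 (camera adjusted p = 6.77e-08, and adjusted p = 0.0215 with an estimated correlation). The called gene was ARR7 (AT1G19050), at 4.51 ± 0.425 CPM with IAA and 8.43 ± 0.720 with both, against 10.9 ± 2.08 in mock and 7.37 ± 0.488 with BL. SNRK2.5 (AT5G63650), a stress-signalling kinase gene, had an interaction of 1.31 (SE 0.140, adjusted p = 9.48e-05), and ACS9 one of -1.92 (SE 0.262, adjusted p = 0.000752). The interaction was called for 298 genes, 125 higher (41.9%) and 173 lower, and the share higher was 58.8% with library totals. The count was 195 without mock replicate 1 and 141 without IAA replicate 1, 185 with all 18 libraries in the fit and 860 with no low-count filter. Of the 2675 genes called for BL alone, 170 (6.36%) had an interaction call, against 1.44% of all tested genes. The interaction uses the same BL and mock libraries that gave the BL calls, so the higher share is no sign of enrichment by itself.

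**Figure D2:**
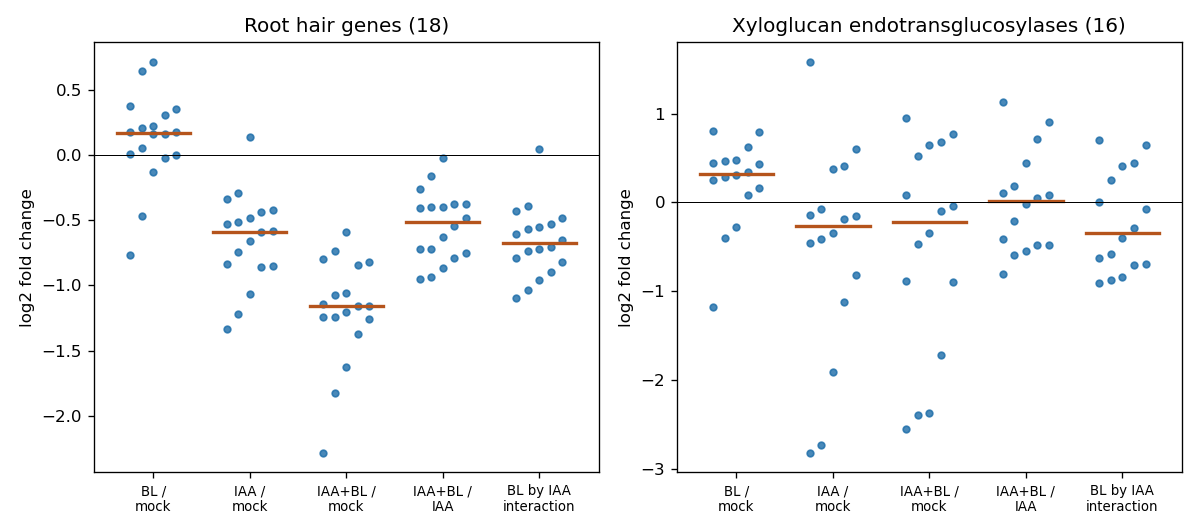
Each point is the log2 fold change of 1 root hair gene (18 genes, left) or 1 xyloglucan endotransglucosylase gene (16 genes, right), and the bar is the list median, for 4 comparisons in Col-0 and for the BL by IAA interaction. The root hair median is 0.17 for BL, -0.59 for IAA and -1.16 for both hormones.

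The 36 bp set asked what brassinosteroid deficiency changes and what BL alters in dwf4 within 4 h. In untreated dwf4, VSP2 (AT5G24770), a jasmonate-responsive storage protein gene, was at 9.81 ± 0.213 CPM against 0.403 ± 0.111 in wild type (log2 fold change 4.60, SE 0.387, adjusted p = 0.000379). BR6OX2 was at 75.5 ± 8.02 CPM against 25.8 ± 1.98 (1.54, SE 0.105, adjusted p = 0.000141). The copper transporter gene COPT2 (AT3G46900) fell to 2.69 ± 0.221 CPM (-3.16, SE 0.154, adjusted p = 4.88e-05), and the glutamine synthetase gene GSR2 (AT1G66200) from 2685 ± 269 to 722 ± 25.9 CPM (-1.90, SE 0.0760, adjusted p = 3.12e-05).

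Of the xylem secondary-wall genes in dwf4, 0 of 15 rose and 10 fell (0 and 11 adjusted over the list alone). The median was -0.53 (camera adjusted p = 1.29e-11, and adjusted p = 0.13 with an estimated correlation). Examples were FLA12 -1.41, FLA11 -0.78, XCP2 -0.64 and CESA4 -0.54, the last a cellulose synthase of xylem walls. Of the suberin genes, 0 of 13 rose and 7 fell (0 and 10 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 3.33e-07, and adjusted p = 0.22 with an estimated correlation), with CYP86A1 -1.03, FAR1 -0.67 and CYP86B1 -0.59. The brassinosteroid-inactivating enzymes had 3 fallers of 3, also adjusted over the list alone (camera adjusted p = 3.33e-07, and adjusted p = 0.22 with an estimated correlation): SOB7 -0.86, BAT1 -1.07 and BAS1, whose change of -0.58 lost its call without wild-type replicate 1 (-0.52) and without wild-type replicate 2 (-0.64). In root hair genes, 7 of 18 members rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 1.95e-06, and adjusted p = 0.467 with an estimated correlation), PRP1 with 0.92. Of the stress and handling genes, 4 of 11 rose and 0 fell (5 and 0 adjusted over the list alone). The median was 0.66 (camera adjusted p = 0.00292, and adjusted p = 0.377 with an estimated correlation). Untreated dwf4 libraries stood apart on some of these genes, with WRKY40 at 25.7 ± 12.3 and WRKY33 at 124 ± 35.9 CPM, but less on MYB51 at 19.5 ± 2.55. They also stood apart on some of the largest rises, with LEA7 at 11.6 ± 10.1, LTI78 at 173 ± 161 and JAZ10 at 20.7 ± 15.5 CPM. In all, 2487 of 19558 genes were called, 937 higher (37.7%) and 1550 lower, and the share higher was 52.2% with library totals. The count was 667 without wild-type replicate 1 and 575 without wild-type replicate 2, 1597 with DESeq2 and 3781 with all 18 libraries in the fit.

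BL given to dwf4 raised the gibberellin-inactivating enzyme gene GA2OX8 from 0.524 ± 0.267 to 9.53 ± 1.98 CPM (log2 fold change 4.15, SE 0.322, adjusted p = 0.000166), SULTR1;1 from 1.70 ± 0.508 to 24.8 ± 2.56 CPM and EXLA2 from 3.27 ± 0.819 to 29.0 ± 0.0761 CPM (3.15, SE 0.157, adjusted p = 2.73e-05). BR6OX2 fell from 75.5 ± 8.02 to 6.51 ± 0.864 CPM (-3.53, SE 0.126, adjusted p = 8.41e-06), and FEZ (AT1G26870), a regulator of root cap stem cells, from 4.57 ± 0.640 to 0.596 ± 0.287 CPM. Other falls were ACS11 -4.74 (from 11.4 ± 7.23 to 0.418 ± 0.0768 CPM), MYB55 -2.88, EXPA10 -2.75 and ARR3 -2.29. Of the Aux/IAA genes, 14 of 25 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 7.77e-15, and adjusted p = 0.114 with an estimated correlation), with IAA5 2.85 and IAA11 1.15. GH3 genes moved with them: 5 of 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 1.19e-13, and adjusted p = 0.11 with an estimated correlation), GH3.2 by 2.66. Of the xyloglucan endotransglucosylase genes, 9 of 16 rose and 1 fell (12 and 1 adjusted over the list alone). The median was 0.75 (camera adjusted p = 1.61e-10, and adjusted p = 0.142 with an estimated correlation). The endodermis list had 6 risers and 0 fallers of 7 (7 and 0 adjusted over the list alone, camera adjusted p = 4.31e-06, and adjusted p = 0.149 with an estimated correlation). Brassinosteroid synthesis had 5 fallers and 0 risers of 10 (0 and 7 adjusted over the list alone, camera adjusted p = 4.32e-17, and adjusted p = 0.11 with an estimated correlation). In the xylem list 0 of 15 genes were called, also adjusted over the list alone, and its median was 0.13 (camera adjusted p = 0.313). Between BL-treated and untreated dwf4, 2602 genes were called, 1537 higher and 1065 lower, with 1323 without BL replicate 1 and 1392 without BL replicate 2. The count was 1643 with DESeq2, 1560 with a fit of the 4 libraries compared alone and 3988 with all 18 libraries. No mock-treated dwf4 was sequenced, so effects of BL and of the treatment itself are confounded in this contrast.

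Against untreated wild type, BL-treated dwf4 still had COPT2 at 3.98 ± 0.597 CPM (log2 fold change -2.60, SE 0.142, adjusted p = 4.54e-05) and CDEF1 (AT4G30140), a cutinase gene, at 6.36 ± 0.569 against 35.4 ± 2.19 CPM. ACS9 was at 21.9 ± 4.38 against 0.729 ± 0.804 CPM, and EXLA2 at 29.0 ± 0.0761 against 8.55 ± 0.715 CPM. Of the xylem genes, 0 of 15 rose and 11 fell (the same adjusted over the list alone). The median was -0.42 (camera adjusted p = 5.27e-07, and adjusted p = 0.192 with an estimated correlation). Of the suberin genes, 0 of 13 rose and 9 fell (1 and 9 adjusted over the list alone). The median was -0.43 (camera adjusted p = 9.98e-07, and adjusted p = 0.192 with an estimated correlation). Of the xyloglucan endotransglucosylase genes, 11 of 16 rose and 1 fell (13 and 1 adjusted over the list alone). The median was 0.88 (camera adjusted p = 2.68e-10, and adjusted p = 0.192 with an estimated correlation). The test called 3674 genes, 1883 higher and 1791 lower. The count was 1034 without wild-type replicate 1, 1084 without wild-type replicate 2, 1789 without BL replicate 1 and 2327 without BL replicate 2, and 2309 with DESeq2.

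A fit of all 18 libraries tested whether the BL response differed between dwf4 and Col-0, although the baselines differ in being untreated or mock-treated and read length coincides with the experiment. BR6OX2 had a difference of -2.16 (SE 0.199, adjusted p = 3.35e-05) on the log2 scale and BEH2 (AT4G36780), a relative of BZR1, one of -1.27 (SE 0.0990, adjusted p = 8.51e-06). GA2OX8 and EXLA2 had larger log2 fold changes in dwf4, by 2.59 (SE 0.411, adjusted p = 0.00438) and 1.84 (SE 0.176, adjusted p = 4.23e-05). Untreated dwf4 already differed from wild type in EXLA2 (-1.38) and BR6OX2 (1.54). With BL, EXLA2 reached 29.0 CPM in dwf4 and 24.5 in Col-0, GA2OX8 9.53 and 6.17, and BR6OX2 6.51 and 10.3. A difference of fold changes does not tell a shifted baseline from a stronger response to BL. Of the Aux/IAA genes, 5 of 26 had a more positive and 0 a more negative response in dwf4 (12 and 0 adjusted over the list alone). The median was 0.41 (camera adjusted p = 1.19e-13, and adjusted p = 0.00401 with an estimated correlation). Of the GH3 genes, 4 of 6 had a more positive and 0 a more negative response in dwf4 (the same adjusted over the list alone), with a median of 1.02 (camera adjusted p = 2.39e-16, and adjusted p = 0.00401 with an estimated correlation), with GH3.2 at 1.67. In brassinosteroid synthesis 0 of 10 genes had a more positive and 3 a more negative response in dwf4 (0 and 5 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 1.04e-13, and adjusted p = 0.0029 with an estimated correlation), with BR6OX2 -2.16, CYP90D1 (AT3G13730) -1.21 and CPD -0.79. The difference was called for 191 of 20393 genes, 129 with a more positive response in dwf4 and 62 with a more negative one. That count was 121 without mock replicate 1, 70 without mock replicate 2, 75 without Col-0 BL replicate 2, 123 and 629 without dwf4 untreated replicates 1 and 2, and 122 and 105 without dwf4 BL replicates 1 and 2. It was 842 with no low-count filter and 43 with a fit of the 8 libraries compared alone.

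In bri1-116, untreated and set against mock-treated Col-0, VSP2 was at 16.5 ± 1.04 against 0.605 ± 0.0385 CPM (log2 fold change 4.77, SE 0.210, adjusted p = 2.24e-10), JAZ10 (AT5G13220) at 26.9 ± 3.77 against 2.18 ± 0.281 CPM (3.61, SE 0.161, adjusted p = 2.41e-10) and TAT3 (AT2G24850) at 11.9 ± 2.58 against 0.851 ± 0.190 CPM. The potassium transporter gene HAK5 (AT4G13420) fell from 29.8 ± 13.8 to 5.25 ± 0.880 CPM, PIN5 (AT5G16530), an auxin transporter of the endoplasmic reticulum, from 4.36 ± 0.0839 to 0.854 ± 0.343 CPM, and ACS5 (AT5G65800) from 4.62 ± 1.35 to 0.864 ± 0.0215 CPM. Of the xylem genes, 0 of 15 rose and 13 fell (the same adjusted over the list alone), with a median of -0.88 (camera adjusted p = 5.13e-18, and adjusted p = 0.0891 with an estimated correlation), with FLA12 -1.38 and XCP2 -1.05. Of the suberin genes, 0 of 13 rose and 12 fell (0 and 13 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 1.37e-16, and adjusted p = 0.0891 with an estimated correlation), with ABCG6 -1.42, CYP86A1 -1.38 and CYP86B1 -1.32. The endodermis list had 6 fallers and 0 risers of 8, also adjusted over the list alone (camera adjusted p = 1.11e-05, and adjusted p = 0.296 with an estimated correlation). Of the root hair genes, 11 of 18 rose and 0 fell (the same adjusted over the list alone). The median was 0.27 (camera adjusted p = 2.46e-05, and adjusted p = 0.296 with an estimated correlation). Of the stress and handling genes, 10 of 12 rose and 1 fell (10 and 2 adjusted over the list alone). The median was 0.56 (camera adjusted p = 4e-04, and adjusted p = 0.296 with an estimated correlation). Of the stem cell and meristem regulators 7 of 15 rose and 2 fell (8 and 2 adjusted over the list alone), PLT3 by 0.75 and PLT2 by 0.68 (camera adjusted p = 0.141). Brassinosteroid inactivation had 3 fallers of 4, also adjusted over the list alone (camera adjusted p = 0.000962, and adjusted p = 0.0891 with an estimated correlation). The test called 7456 of 20644 genes, 3443 higher and 4013 lower, 1219 by more than 2-fold.

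The double mutant was compared with bri1-116, both untreated, for what bzr1-1D changes in the receptor mutant. ACS5 rose from 0.864 ± 0.0215 to 6.44 ± 0.207 CPM (log2 fold change 2.89, SE 0.251, adjusted p = 1.74e-07), PSBO2 (AT3G50820), a photosystem II subunit gene, from 3.44 ± 0.382 to 23.2 ± 0.647 CPM (2.75, SE 0.120, adjusted p = 1.58e-10) and the amino acid transporter gene UMAMIT17 (AT4G08300) from 25.6 ± 1.72 to 137 ± 8.05 CPM (2.42, SE 0.0680, adjusted p = 1.94e-12). DIR5 (AT1G64160), a dirigent protein gene, fell from 25.3 ± 5.28 to 0.288 ± 0.0259 CPM, ACS11 from 6.11 ± 0.262 to 0.250 ± 0.0283 CPM and CYP90D1, of brassinosteroid synthesis, from 36.2 ± 6.27 to 6.44 ± 0.207 CPM (-2.49, SE 0.167, adjusted p = 1.11e-08). The peptidase gene scpl30 (AT4G15100) was at 9.60 ± 3.47 CPM in bri1-116 and had no counts in either library of the double mutant. Of the xylem genes, 12 of 15 rose and 0 fell (13 and 0 adjusted over the list alone). The median was 0.92 (camera adjusted p = 9.6e-14, and adjusted p = 0.202 with an estimated correlation). Of the suberin genes, 11 of 13 rose and 0 fell (the same adjusted over the list alone). The median was 0.69 (camera adjusted p = 1.65e-07, and adjusted p = 0.217 with an estimated correlation). Shoot-type photosynthesis genes had 10 risers of 10, also adjusted over the list alone (camera adjusted p = 4.71e-10, and adjusted p = 0.217 with an estimated correlation). Of the stem cell and meristem regulators, 1 of 15 rose and 10 fell (the same adjusted over the list alone), with a median of -0.60 (camera adjusted p = 0.0014, and adjusted p = 0.217 with an estimated correlation), with PLT3 -1.27, PLT5 -1.21 and PLT2 -1.02. Of the stress and handling genes, 0 of 12 rose and 8 fell (0 and 9 adjusted over the list alone). The median was -0.52 (camera adjusted p = 3e-05, and adjusted p = 0.217 with an estimated correlation). The test called 8316 genes, 4367 higher and 3949 lower, 1552 by more than 2-fold.

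Against mock-treated Col-0, the untreated double mutant had the small Rubisco subunit gene RBCS1A (AT1G67090) at 20.9 ± 1.66 against 3.25 ± 0.598 CPM (log2 fold change 2.66, SE 0.240, adjusted p = 1.61e-06), LHCB1.3 (AT1G29930), a light-harvesting protein gene, at 46.2 ± 5.06 against 8.45 ± 1.64 CPM (2.43, SE 0.169, adjusted p = 1.28e-07) and the sugar transporter gene SWEET11 (AT3G48740) at 38.2 ± 3.86 against 9.15 ± 0.715 CPM. All 10 measured photosynthesis genes rose, also adjusted over the list alone, with a median of 1.49 (camera adjusted p = 1.03e-34, and adjusted p = 0.0423 with an estimated correlation). CYP90D1 fell from 31.3 ± 2.42 to 6.44 ± 0.207 CPM and GSTF14 (AT1G49860) from 22.0 ± 9.86 to 1.32 ± 0.676 CPM. In the xylem list 0 of 15 genes were called, also adjusted over the list alone (median -0.07, camera adjusted p = 0.935). Of the suberin genes, 0 of 13 rose and 6 fell (the same adjusted over the list alone). The median was -0.25 (camera adjusted p = 0.00304, and adjusted p = 0.58 with an estimated correlation). BR6OX2 was at 26.3 ± 1.65 CPM against 25.9 ± 1.16 (adjusted p = 0.912). The test called 3343 genes, 1657 higher and 1686 lower, with 1975 without mock replicate 1, 1609 without double mutant replicate 1 and 1774 without double mutant replicate 2, and 2197 with DESeq2.

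**Figure D3:**
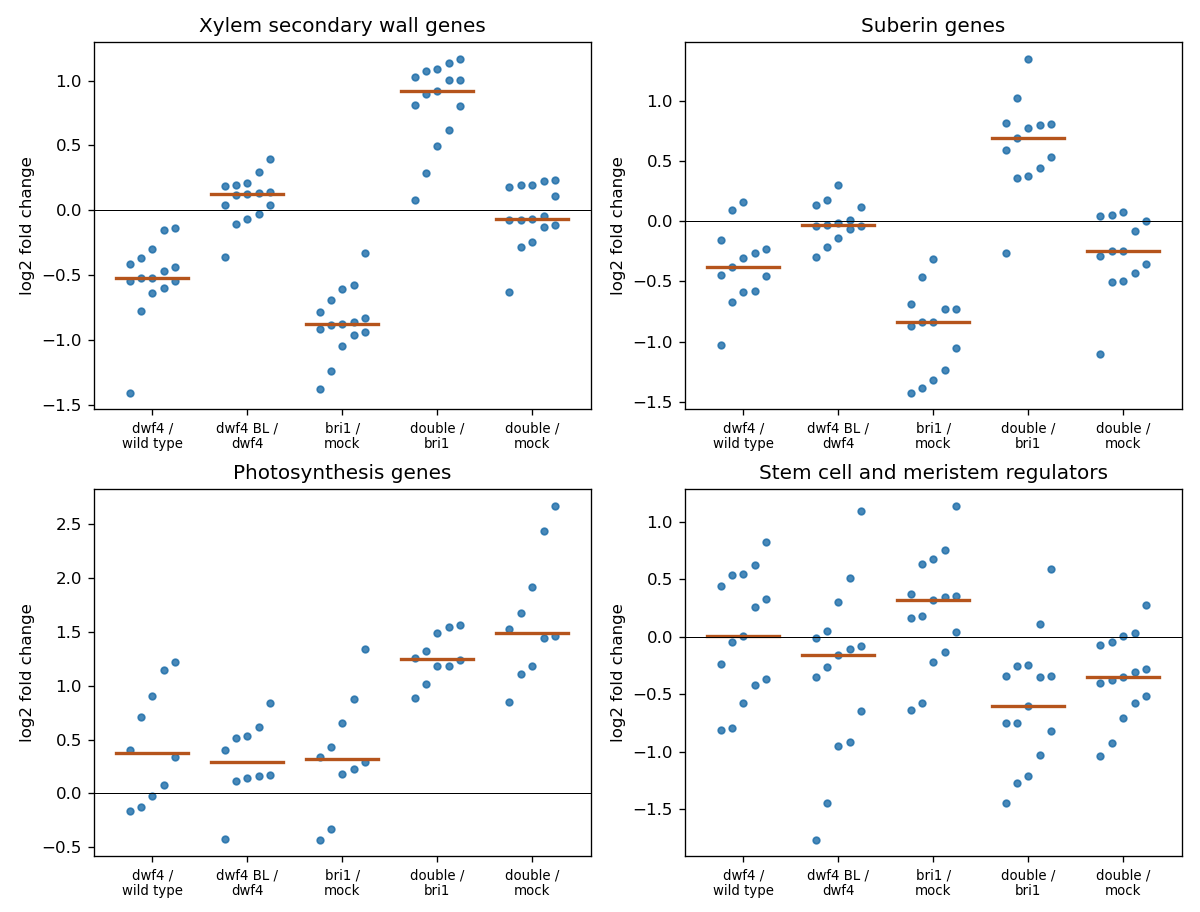
Each point is the log2 fold change of 1 gene of the xylem secondary-wall, suberin, photosynthesis or stem cell and meristem regulator list, and the bar is the list median, for 5 comparisons of the mutants. The xylem median is -0.53 in dwf4, -0.88 in bri1-116 and 0.92 in the double mutant against bri1-116.

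Fold changes were then compared across genes, which are not independent replicates. The BL responses in dwf4 and Col-0, which share no library, correlated at r = 0.61 over 19502 genes (Spearman's rho 0.569). Of 1254 genes called in both, 1251 (99.8%) had the same direction, such as SULTR1;1, EXLA2, BR6OX2 and ARR3. Genes called higher in both numbered 735 against 102 expected from the list sizes, and genes called lower in both 516 against 73.8. The change from bri1-116 to the double mutant and the BL response in Col-0, which also share no library, correlated at r = 0.238 (rho 0.366), or 0.351 over genes with a mean of at least 2 CPM. Of the 1873 genes called in both, 1689 (90.2%) had the same direction, with 775 higher in both against 278 expected and 914 lower in both against 260 expected. ACS11, PLT2 and PLT3 were lower in both. The dwf4 and bri1-116 differences correlated at r = 0.572 (rho 0.501), and 1757 of 1852 genes called in both (94.9%) had the same direction, such as VSP2, TAT3, XCP2 and CYP86A1.

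For BL and IAA in Col-0, EXLA2 (1.32 and -1.69), YUC3 (1.35 and -1.21) and XTH17 (0.44 and -2.82) changed in opposite directions. GA2OX8 (1.57 and 2.62) rose with both. Of 2163 genes called for both hormones, 1676 had opposite directions and 487 the same. Genes higher with BL and lower with IAA numbered 873 against 386 expected, and the reverse 803 against 407, while 189 were higher in both against 394 and 298 lower in both against 399. Both contrasts use the mock libraries, which alone gave r = 0.452 and a covariance of 0.0143 in 10 simulated draws of unchanged groups. The observed r was -0.048 (rho -0.233) and the covariance -0.0158, and the difference of the covariances, -0.0301, estimates the part not made by the shared control. The sign of r turned without mock replicate 1 (0.103) and without mock replicate 2 (0.07), where both contrasts rest on the same single mock library. With a separate mock library for each contrast, a split chosen after the results were seen, r was -0.105 and -0.048 and the covariance -0.0448 and -0.0192. With the BL response taken from dwf4, which shares no library with the IAA contrast, r was -0.134 (rho -0.237), and 1407 of 2009 genes called in both had opposite directions. There, 996 genes were higher with BL and lower with IAA against 469 expected, and 411 the reverse against 319, while 368 were lower in both against 325 (Fisher's exact p = 0.0036) and 234 higher in both against 461. The change from bri1-116 to the double mutant also ran against the IAA response, at r = -0.319, with 4770 of 5981 genes called in both opposite in direction, EXLA2 (1.77) and ACS5 (2.89) among them. This pair shares no library. The dwf4 difference from wild type shares none with the IAA contrast either, and its correlation with IAA was weak, at r = 0.056 (rho 0.094). Of 1812 genes called in that pair, 1050 (57.9%) had the same direction. The bri1-116 difference, which shares the mock libraries with the IAA contrast, correlated with it at r = 0.248 (rho 0.276). For that pair, 3701 of 5188 genes called in both (71.3%) had the same direction. Sharing alone gave r = 0.497 in simulated unchanged groups, and the covariance above the simulated one was 0.119. With a separate mock library for each, r was 0.197 and 0.224. The bri1-116 libraries are also the baseline of the double mutant contrast.

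**Figure D4:**
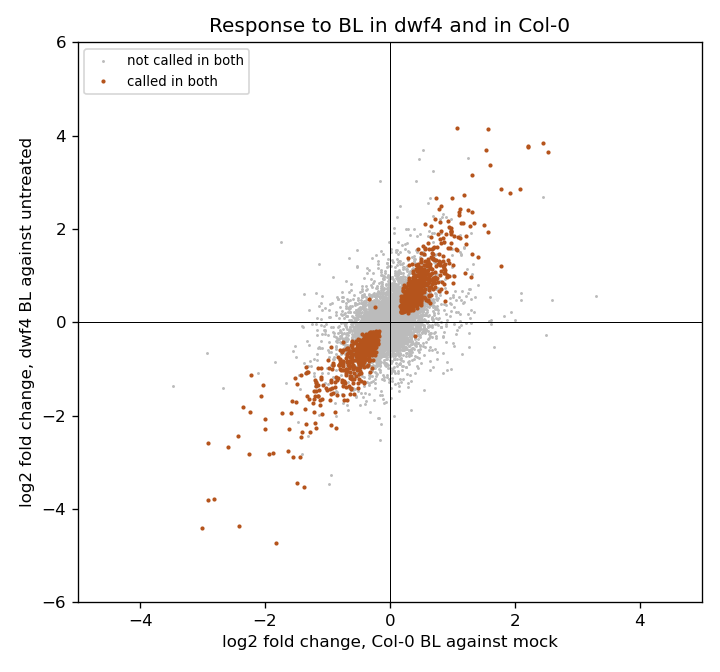
Each point is 1 of 19502 genes, placed by its log2 fold change with BL in Col-0 (horizontal) and in dwf4 (vertical), with the 1254 genes called in both in orange. All but 3 of the orange points lie in the quadrants of like sign.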

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

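The tests below on mature root tissue, scaling, untreated against mock-treated libraries and section position were chosen after their results were seen. The other tests of explanations were written after the pattern was seen but before the value they measure. Standard errors of list medians are taken across genes, which are not independent, so these errors are too small.

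In Col-0 the response to BL differed with IAA present for 298 genes, by a test of the interaction itself. The largest positive interactions on the log2 scale were CYP78A10 2.62, UMAMIT35 1.57, WAKL5 1.53, ARR7 1.48, SNRK2.5 1.31 and ACS2 1.05. The largest negative ones were GSTU14 -2.37, ACS9 -1.92, NCED9 -1.57, WOX11 -1.50, QWRF7 -1.40 and RHS8 -1.31. Lists that differed, also with an estimated correlation, were the cytokinin list (median 0.36, adjusted p = 0.0215) and the root hair list (median -0.68, adjusted p = 0.0197). The calls of GSTU14, ACS9, NCED9, ARR7, SNRK2.5 and ACS2 held without each library in turn. Calls were lost without mock replicate 1 (CYP78A10 2.61 and UMAMIT35 1.49), without mock replicate 2 (CYP78A10 2.65, WAKL5 1.42 and WOX11 -1.31), without Col-0 BL replicate 1 (CYP78A10 2.33, WOX11 -1.16 and QWRF7 -1.17) and without Col-0 BL replicate 2 (CYP78A10 2.79). They were also lost without IAA replicate 1 (CYP78A10 2.42, UMAMIT35 1.61 and WAKL5 1.67), without IAA replicate 2 (WAKL5 1.45, QWRF7 -1.29 and RHS8 -1.15), without IAA plus BL replicate 1 (QWRF7 -1.24 and RHS8 -1.29) and without IAA plus BL replicate 2 (RHS8 -1.33). The count of 298 was 195 without mock replicate 1 and 141 without IAA replicate 1.

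The response to BL also differed between dwf4 and Col-0, for 191 genes, by a test of the difference in a fit of all 18 libraries. More positive in dwf4 were GA2OX8 2.59, GH3.3 2.33, LPAT3 1.94, EXLA2 1.84, PERK4 1.76 and HSFA6B 1.74, and more negative were BR6OX2 -2.16, IGMT2 -1.81, CLE2 -1.44, MYB55 -1.34, BEH2 -1.27 and IPT7 -1.25. Lists that differed, with medians on the log2 scale, were GH3 1.02, Aux/IAA 0.41, brassinosteroid inactivation 0.61 and brassinosteroid synthesis -0.32, with adjusted p = 0.00401, 0.00401, 0.028 and 0.0029 with an estimated correlation. Untreated dwf4 already differed from wild type in EXLA2 (-1.38), BR6OX2 (1.54) and BEH2 (0.88). A shifted baseline and a stronger response to BL are therefore not told apart by this test. GA2OX8, EXLA2, BR6OX2 and BEH2 kept their calls without each library in turn. Calls were lost without mock replicate 1 (LPAT3 1.93 and IPT7 -1.27), without mock replicate 2 (GH3.3 2.19, LPAT3 1.93, PERK4 1.41, HSFA6B 1.18, IGMT2 -1.70, MYB55 -1.35 and IPT7 -1.24), without Col-0 BL replicate 1 (GH3.3 2.23 and HSFA6B 1.60) and without Col-0 BL replicate 2 (GH3.3 2.38, LPAT3 1.81, HSFA6B 1.82, MYB55 -1.14 and IPT7 -1.04). They were also lost without untreated dwf4 replicate 1 (GH3.3 2.09, LPAT3 1.90, IGMT2 -1.37 and IPT7 -1.09), without BL-treated dwf4 replicate 1 (GH3.3 2.08, LPAT3 1.95, HSFA6B 1.54 and IPT7 -1.17) and without BL-treated dwf4 replicate 2 (LPAT3 1.91, IGMT2 -1.59, CLE2 -1.16, MYB55 -1.13 and IPT7 -1.35). The count of 191 ranged from 70 without mock replicate 2 to 629 without untreated dwf4 replicate 2, and the other libraries that moved it over 1.5 times were mock replicate 1 (121), Col-0 BL replicate 2 (75), untreated dwf4 replicate 1 (123), and BL-treated dwf4 replicates 1 (122) and 2 (105).

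Root hair genes such as EXPA7, PRP1 and MRH6 fell with BL in the presence of IAA and had negative interactions, with a list median of -0.68 (SE 0.079, n = 18 genes). Sections with less mature tissue could lower hair genes, but xylem, suberin and endodermis genes, also of mature tissue, had a pooled interaction median of -0.002 (SE 0.053, 36 genes). The pattern did not rest on 1 library, since the median closest to 0 without any of the 8 libraries was -0.575 (range -0.753 to -0.575). It did not come from genes near the count floor either, with -0.654 (SE 0.083) over the 17 genes at 5 CPM or more in each of the 4 groups. A hormone interaction in hair-forming cells remains as a hypothesis, which counts from sorted hair cells of the 4 Col-0 treatments may decide.

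Xylem and suberin genes such as FLA12, XCP2 and CYP86A1 were lower in dwf4 and in bri1-116 (pooled median -0.867 in bri1-116, SE 0.071, 28 genes) and higher again in the double mutant (0.802 against bri1-116). The use of mock-treated controls for bri1-116 could have made the difference, but dwf4 and its wild type were both untreated and gave -0.451 (SE 0.074). Scaling shifts all genes alike, so it cannot make a difference between lists. The pooled median lay below that of the mitotic list in bri1-116, at a difference of -0.736 (SE 0.089 across genes). If the section of a short root held tissue nearer the tip, mitotic genes could be higher. Their median in bri1-116 was -0.131 (SE 0.055, 20 genes), while stem cell regulators had 0.319 (SE 0.157). Root hair genes, also of mature tissue, rose on balance in dwf4 and bri1-116, against such a shift. Endodermis genes mostly fell in bri1-116, as such a shift would have it. The position of the section and lower expression per cell therefore cannot be told apart. Brassinosteroid action on these tissues is a hypothesis that counts from sections at a matched distance from the tip would decide.

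Photosynthesis genes such as RBCS1A and LHCB1.3 were higher in the double mutant than in both bri1-116 and mock-treated Col-0. Shoot tissue in the sections could bring them, but only 6 of the other shoot-type genes reached 2 CPM. Their median against bri1-116 was -0.032 (SE 0.556), with PDF1 at -1.83 and CER1 at 0.80. Some of them were present in mock-treated Col-0 roots, PDF1 at 58.8 and CER3 at 23.0 CPM, so they tell little about shoot tissue. YAB1, YAB2, YAB3, YAB5, FAMA and GL1 did not pass the low-count filter, and TMM stayed under 1 CPM. The origin of the rise therefore remains open. Mock treatment of the control was excluded as the whole cause by the untreated bri1-116 libraries, against which the list median was 1.245 (SE 0.087, 10 genes). No 1 library made it, since the lowest median without any library was 1.138 (range 1.138 to 1.252). Greening of the root in the double mutant is a hypothesis that these counts do not test, and chlorophyll measured in roots cut free of shoot tissue would decide it.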

How the results depend on the processing

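Each count below is of genes called, and the cause of a change was not tested unless stated. DESeq2 size factors, library totals, a mean of at least 2 CPM and the replicate number as a block left all 13 counts within 1.5 times their value. No named gene turned direction where it was called with the main or the alternative setting. For the named genes and the list members added to them, 1705 pairs of a gene and a comparison gave 24596 values. Of these, 22445 kept their side of the threshold. The genes were picked for large changes or a small adjusted p, so this share does not describe all genes. A further 1881 lost the call, 270 gained it and 0 reversed while called. Changes of sign in genes called with neither setting were not counted. The replicate number as a block ended 30 of these calls and made 6. Residuals of equal numbers correlated at -0.193 to 0.174 over 15 pairs of groups at 101 bp (median -0.039) and at -0.193 to 0.030 over 3 pairs at 36 bp. These values gave no sign of a common pairing by number. No reference spread was computed for them, so a weak pairing could be missed. Simulated 1.5-fold changes were recovered in 30.3% to 34.1% of cases in the 3 comparisons at 36 bp, in 58.3% to 80.9% in those of 2 groups at 101 bp, in 40.3% for the interaction and in 34.8% for the difference of BL responses, so small changes can be missed.

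At an adjusted p of 0.01, which is stricter by construction, the counts were 1170 for BL, 1036 for BL in the presence of IAA, 132 for the interaction, 931 for dwf4 against wild type, 1041 for BL in dwf4, 1547 for BL-treated dwf4 against wild type, 1711 for the double mutant against mock and 52 for the difference of BL responses. Against a fold change of 1.5, stricter by construction as well, they were 79 for BL, 3581 for IAA, 2984 for both hormones, 160 for BL in the presence of IAA, 3546 for IAA in the presence of BL, 17 for the interaction, 183 for dwf4, 281 for BL in dwf4, 350 for BL-treated dwf4 against wild type, 1204 for bri1-116, 1439 for the double mutant against bri1-116, 294 against mock and 10 for the difference of BL responses. DESeq2 gave 1679 for BL, 1597 for dwf4, 1643 for BL in dwf4, 2309 for BL-treated dwf4 against wild type and 2197 for the double mutant against mock. With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, the counts were 1577 for BL, 1560 for BL in dwf4 and 43 for the difference of BL responses. All 18 libraries in the fit gave 185 for the interaction, 3781 for dwf4 and 3988 for BL in dwf4. Without a low-count filter the interaction had 860 and the difference of BL responses 842.

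Leaving out each library in turn gave 1150 to 2350 for BL, 10092 to 10829 for IAA, 8243 to 9878 for both hormones, 1099 to 1529 for BL in the presence of IAA, 9420 to 10895 for IAA in the presence of BL and 141 to 348 for the interaction. It gave 575 to 2359 for dwf4, 1323 to 2927 for BL in dwf4, 1034 to 2327 for BL-treated dwf4 against wild type, 5413 to 5762 for bri1-116, 5875 to 6627 for the double mutant against bri1-116, 1609 to 2242 against mock and 70 to 629 for the difference of BL responses. Of 377 tests of gene lists, 150 were called with the preset correlation, 19 with the estimated one, 207 with the directional form of fry and 328 with its mixed form. The directional form ended 22 of the 150 calls and made 79.

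The correlation of the BL responses in dwf4 and Col-0, 0.61, was 0.777 over genes called in either and 0.476 to 0.587 without 1 library. That of the double mutant against bri1-116 with BL, 0.238, was 0.351 at a mean of at least 2 CPM and 0.176 to 0.251 without 1 library. BL and IAA, at -0.048, gave -0.088 to 0.103 and turned sign without mock replicate 1 (0.103) and without mock replicate 2 (0.07). The pair of bri1-116 against mock with BL, at -0.095, gave -0.131 to 0.107 and turned sign without mock replicate 1 (0.102) and without mock replicate 2 (0.107). These 2 contrasts share the mock libraries, which alone gave 0.458 in simulated unchanged groups, and the covariance above the simulated one was -0.0343. Of 1678 genes called in both with the shared mock, 1436 had opposite directions. With a separate mock library for each, r was -0.12 and -0.15. BL in dwf4 with IAA gave -0.139 to -0.091, and dwf4 with bri1-116 gave 0.49 to 0.59.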

Other observations

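Single genes for ethylene-precursor synthases changed in both directions. BL raised ACS9 (2.53) and ACS5 (1.19) and lowered ACS11 (-1.82) in Col-0. In dwf4 it raised ACS9 (3.64) and ACS5 (2.72) and lowered ACS11 (-4.74). The size of this fall is uncertain, since the untreated dwf4 libraries stood apart on ACS11 (11.4 ± 7.23 CPM) and the BL-treated level of 0.418 CPM was near the floor. IAA raised ACS6 (2.27) and lowered ACS5 from 4.62 ± 1.35 to 0.116 ± 0.00619 CPM, which is near the floor. As a list, 7 of 11 ethylene genes rose and 2 fell (the same adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.00366, and adjusted p = 0.0662 with an estimated correlation) with IAA. The kinase genes WAG1 and WAG2, which act on auxin transport, rose with BL in dwf4 (2.36 and 2.36) and in Col-0 (1.11 and 1.31).

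Auxin synthesis genes moved with BL: 3 of 9 of them rose and 0 fell (the same adjusted over the list alone), with a median of 0.37 (camera adjusted p = 2.18e-05, and adjusted p = 0.0667 with an estimated correlation) in Col-0, and 6 of 9 of them rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 4.47e-07, and adjusted p = 0.111 with an estimated correlation) in dwf4. The phloem sucrose transporter gene SUC2 was lower in dwf4 (-0.90) and bri1-116 (-1.18) and higher in the double mutant than in bri1-116 (1.69). Of the growth-related bHLH list, 1 of 7 genes rose with BL and 3 fell (the same adjusted over the list alone), with a median of -0.51 and a mean of -0.11 (camera adjusted p = 0.0242, and adjusted p = 0.288 with an estimated correlation). BEE1 rose (2.21, a call lost without Col-0 BL replicate 1 at 1.75) while PRE3 (-0.75) and IBH1 (-0.51) fell.

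The test of the following hypothesis was written before its value was seen. Plants that lack their own brassinosteroid may respond more to BL in the genes that bzr1-1D changes in bri1-116, and over 8067 genes called there and also tested in the 36 bp libraries, signed by their direction, the mean BL effect was 0.157 in dwf4 and 0.140 in Col-0, a paired difference of 0.017 (SE 0.00381). This met the prediction but was small, and no other gene set was compared. Splits by size and direction were not part of the prediction. Over the 1306 genes that differed more than 2-fold the difference was 0.065 (SE 0.0167). It was 0.113 (SE 0.0206) over the 651 higher genes of these and 0.018 (SE 0.0262) over the 655 lower ones. Genes are not independent, so these errors are too small, and the controls and read lengths of the 2 experiments differ, so the cause remains open.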
